A study of Capra hircus with 2 samples.

How the data were processed

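The series holds 1 DMRT1 ChIP library and 1 input library from goat primary Sertoli cells. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, and libraries were made from input and immunoprecipitated DNA. The protocol also mentions a control with rabbit IgG, which was not analysed here. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, MACS2, bedtools and HOMER, with no roles or order. STAR is an aligner made for spliced RNA reads, and how it was set for these DNA reads is not given in the sources used here. The genome build, the version and settings of MACS2 and the number of reads per library are likewise not given in the sources used here.

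The authors deposited 3227 peaks called on the 1 ChIP library, a table of merged peaks and a table of peaks with assigned genes. The merged table held the same 3227 intervals. For each peak, the deposited fold enrichment is a ratio of ChIP pileup to local background, per the file headers and values. The p-value and the false discovery rate of each peak are also those of the authors' peak caller. The pileup is the deposited signal, a whole number of fragments from 6 to 302, and whether it was scaled between libraries is not given in the sources used here. Every deposited p-value lay under 0.001. Background per peak was recovered from fold enrichment and pileup, with the pseudocount of 1 that MACS2 adds to both. With this background the Poisson probability of a higher pileup matched the deposited p-value of all 3227 peaks within 0.001 on the log10 scale. The lowest background, 1.32 fragments, was shared within 0.001 by 466 peaks (14.4%) and is called the background floor.

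The annotated table assigned a gene to 2949 peaks, with a signed distance to the TSS of the assigned transcript. A negative distance was read as upstream, the convention of HOMER. Start positions in the annotated table were 1 bp above those of the peak table in 100% of its peaks. Positions printed here are those of the peak table and count from 1. Of the 2949 assigned peaks, 2830 were annotated to the single exon of 29 records, 1 per autosome, and the shortest span of peaks on such a record was 29.7 Mb. No autosomal peak was called intronic or intergenic, so those words were not used.

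Gene names were taken from the authors' table and matched to a RefSeq gene table of the goat assembly ARS1.2, in which 2071 of the 2102 assigned names were found. That table was used for gene kind, gene length, neighbouring genes and chromosome names, and none of its positions is printed. A sequence was given a chromosome where it had at least 2 assigned genes and at least 95% of them were on 1 chromosome in the gene table. A sequence with no assigned gene therefore counts as unplaced. The X chromosome took up 2 sequences. The distance of peaks to gene ends and the share of peaks with a DMRT1 motif were planned and were not analysed here, because no genome or annotation of the build was used. For the same reason the share of peaks within 5 kb of a TSS has no test against random positions and is described only.

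Genes named in the text followed a rule fixed before the data were examined. SPRY1 and DMRT1 were always named. So were all members with a peak (at most 8 a list) of the lists of receptor tyrosine kinase and MAPK feedback, NF-κB pathway, cytokine and adhesion, innate sensor, Sertoli cell and blood-testis barrier genes. Up to 3 were named from each of the granulosa, Leydig, germ cell, leukocyte, myoid and endothelial, and retinoic acid lists. The rule also took the 10 named protein-coding genes of highest fold enrichment and the 3 genes with the most peaks. Because the latter were tRNA names, the 3 protein-coding genes with the most peaks were added. Genes named as having no peak, and the genes close to a TSS other than those of the rule, were picked after the values were seen.

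The 12 lists held 211 genes, of which 199 were in the gene table. Each list was tested with Fisher's exact test, two-sided, for having an assigned peak, against the 20566 protein-coding genes of the table, with Benjamini-Hochberg adjustment over the 12 lists and a threshold of 0.05. The test was checked on simulated data, in which 200 runs planted peaks in the NF-κB list. With 20%, 40% and 60% of its members planted, 34.5%, 99.5% and 100% of runs found the list, and 0.045, 0.035 and 0.055 other lists per run were called. The runs gave every gene outside the list the same independent chance of a peak, 7.31%. In the data long genes had a peak more often and peaks clustered, so these counts do not measure false calls on the data. Shares have 95% Wilson intervals, which cover counting error only. Pileups this low limit the precision of each peak's fold enrichment. Alternatives were a stricter FDR of 1e-05, a fold enrichment of at least 5, a window of 1 kb, chromosomes only, overlap of merged peaks by at least 50% of the shorter interval, and 10000 random gene lists matched on gene length in 10 bins. Peaks with an FDR under 0.05 and peaks of protein-coding genes were alternatives added after the data were seen. Correlations across chromosomes used permutation tests with 100000 resamples. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.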

Results

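DNA bound by DMRT1, a DM-domain transcription factor of Sertoli and germ cells, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary Sertoli cells from the testis of male goats (Capra hircus). Sertoli cells are the somatic cells that nurse germ cells in the seminiferous tubule, and these had been made to overexpress a FLAG-tagged protein. There was 1 ChIP library and 1 input library, so no value below has a replicate error, and every statement describes this pair of libraries. The labels differ on the tag and the antibody. The protocol names anti-Flag beads and the sample label names a DMRT1 antibody, while the tagged protein is given as Dmrt1 for the input and as Dmrt2 for the ChIP. The ChIP is called the DMRT1 ChIP here. The study asked whether DMRT1 acts on SPRY1 and on NF-κB signalling in keeping immune balance in the testis, and its design text points to binding close to gene starts and ends.

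The peak list held 3227 peaks, each with the authors' own fold enrichment, p-value, false discovery rate (FDR) and pileup, which is the number of overlapping fragments at the peak. Sequencing depth per library is unknown, but the pileups were low, with a median of 9 fragments and quartiles of 8 and 10. The median fold enrichment over background was 3.59, with quartiles of 3.23 and 4.07. Peaks were short, with a median length of 177 bp, and 1152 of them had the minimum length of 157 bp. Of the 3227 peaks, 913 had an FDR under 0.05, which is 28.3% (95% Wilson interval 26.8% to 29.9%), and 286 had an FDR under 0.01. A further group of 1059 peaks, 32.8% of the list, had an FDR of 0.25 or more. Autosomes carried 2919 peaks, the X chromosome carried 15, and 293 lay on 280 sequences not placed on a chromosome. An FDR under 0.05 was reached by 54.6% of the peaks on unplaced sequences and by 25.7% of those on chromosomes (Fisher's exact test, two-sided, p = 2.59e-23). Median fold enrichment was 3.59 on both kinds of sequence, whereas median pileup was 13 on unplaced sequences and 9 on autosomes.

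**Figure D1:**
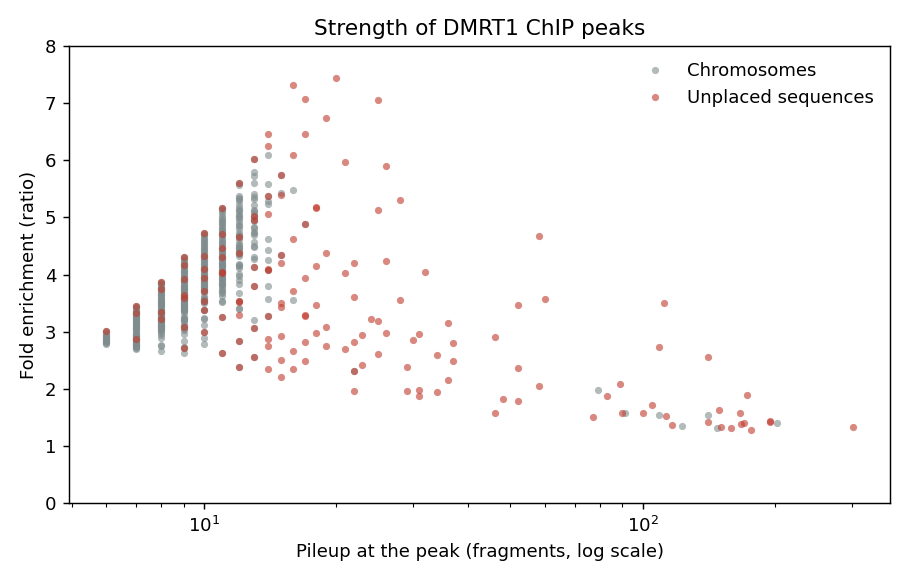
Fold enrichment (ratio, y axis) against pileup (fragments, log scale, x axis) for the DMRT1 ChIP peaks. Each point is a distinct pair of values, grey for peaks on chromosomes and red for peaks on unplaced sequences. Of the peaks with a pileup of 50 or more, 29 lay on unplaced sequences and 7 on autosomes.

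SPRY1, a sprouty protein that restrains receptor tyrosine kinase and MAPK signalling, had 6 assigned peaks on chromosome 17, none of them near its promoter. The nearest lay 77.9 kb downstream of the transcription start site (TSS), at positions 36820830 to 36821118, with a fold enrichment of 3.71 and an FDR of 0.0897. A peak 117 kb upstream, at 36624819 to 36625008, had a fold enrichment of 3.997 and an FDR of 0.0638. An FDR under 0.05 was reached by 2 of the 6 peaks, both far downstream. The strongest, at 37215616 to 37215772, lay 473 kb from the TSS with a fold enrichment of 4.73 and an FDR of 0.0103. The other, at 37255547 to 37255747, lay 513 kb from the TSS with a fold enrichment of 4.03 and an FDR of 0.0451. The remaining peaks, 170 kb and 451 kb downstream, had fold enrichments of 2.72 and 3.28 and FDRs of 0.489 and 0.261. The outermost SPRY1 peaks were 631 kb apart. Among protein-coding genes, 3 had more assigned peaks than SPRY1, and 4, SPRY1 included, had as many. A gene's number of assigned peaks also depends on how far away the neighbouring TSSs lie, so this rank is no measure of binding. The genome build behind these positions is not given in the sources used here. No peak was assigned to DMRT1 itself.

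**Figure D2:**
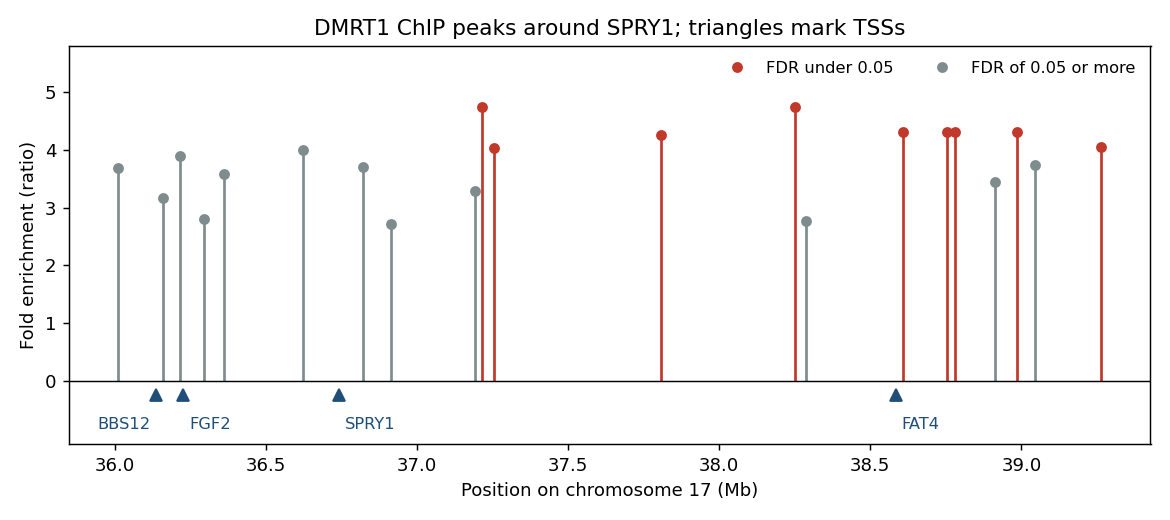
DMRT1 ChIP peaks on chromosome 17 around SPRY1 (position in Mb, x axis; fold enrichment as a ratio, y axis). Each stem is 1 peak, red where the FDR is under 0.05 and grey otherwise, and triangles mark the TSS of named protein-coding genes with a peak, as implied by the authors' distances. The nearest peak to SPRY1 lies 77.9 kb from its TSS.

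SPRY2, RASA1 and DUSP10 were the other members of the list of receptor tyrosine kinase and MAPK feedback genes with an assigned peak. SPRY2, a close relative of SPRY1, had 5 peaks on chromosome 12, the nearest 120 kb from its TSS. Their fold enrichments ran from 2.62 to 3.89, and none had an FDR under 0.05. RASA1, which encodes a RAS GTPase-activating protein, had 3 peaks on chromosome 7. The strongest of these lay 222 kb upstream at 23867529 to 23867738, with a fold enrichment of 5.11 and an FDR of 0.000819. DUSP10, a MAP kinase phosphatase, had a peak 92.2 kb upstream with a fold enrichment of 4.06 and an FDR of 0.0422. A further DUSP10 peak lay 432 kb downstream, with a fold enrichment of 3.23 and an FDR of 0.261. SPRY4 and DUSP6 had no assigned peak. In all, 4 of the 22 list members had a peak, 18.2% against 7.30% of other protein-coding genes (odds ratio 2.82). That difference did not pass the test (Fisher's exact test, two-sided, p = 0.0725, Benjamini-Hochberg adjusted p = 0.870 over 12 lists). With peaks of FDR under 0.05, a setting chosen after the data were seen, SPRY1, RASA1 and DUSP10 kept a peak and the odds ratio was 7.37 (Fisher's exact test, p = 0.0107, adjusted p = 0.128). With a fold enrichment of at least 5 it was 23.2 and rested on RASA1 alone (Fisher's exact test, p = 0.0450, adjusted p = 0.270). The study itself names SPRY1, so this list is not independent of the study's choice of gene. None of the 4 genes had a peak within 5 kb of its TSS.

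NF-κB pathway genes with an assigned peak were MAP3K7, IKBKB, NFKBIZ and BIRC2. MAP3K7, which encodes the kinase TAK1, had the strongest, 43.1 kb upstream on chromosome 9 at 46918006 to 46918221, with a fold enrichment of 4.62 and an FDR of 0.00881. IKBKB, which encodes a catalytic subunit of the IκB kinase, had a peak 9.46 kb upstream on chromosome 27, with a fold enrichment of 3.59 and an FDR of 0.132. NFKBIZ, an atypical IκB protein, had a peak 92.2 kb downstream, with a fold enrichment of 2.84 and an FDR of 0.261. BIRC2, a ubiquitin ligase of the pathway, had peaks 25.2 kb and 65.4 kb downstream with fold enrichments of 3.04 and 3.31, both at an FDR above 0.25. NFKB1, RELA and NFKBIA were among the members with no assigned peak. The 4 genes made up 10.3% of the 39 list members, against 7.31% of other protein-coding genes (odds ratio 1.45, Fisher's exact test, adjusted p = 1). In simulated data a list of this size was found in 34.5% of runs when 20% of its members were given a peak, and in 99.5% of runs at 40%. Those runs ignored gene length and clustering of peaks, so they are a rough guide only.

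TLR1, a receptor for bacterial lipopeptides, had a peak close to its TSS. It lay 1.48 kb downstream on chromosome 6, at 58614180 to 58614379, with a fold enrichment of 4.60 and an FDR of 0.00538. It was the 1 gene with a peak among the 20 innate sensors tested, and TLR2 and TLR4 had none. IL12A, a subunit of interleukin 12, was the 1 gene with a peak among 23 cytokine and adhesion genes. Its peak lay 29.3 kb downstream on chromosome 1, with a fold enrichment of 3.23 and an FDR of 0.261. IL6, TNF and IL1B had no assigned peak. Neither list passed the test against other protein-coding genes (Fisher's exact test, odds ratios 0.667 and 0.576, adjusted p = 1 for both). PTPRC and the other 8 leukocyte markers tested had no peak.

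CDH2, which encodes N-cadherin, a protein of Sertoli cell junctions, carried one of the strongest peaks assigned to a gene. It lay 352 kb upstream on chromosome 24, at 28631452 to 28631680, with a fold enrichment of 5.60 and an FDR of 0.000364. A CDH2 peak 194 kb upstream, at 28789460 to 28789616, had a fold enrichment of 4.73 and an FDR of 0.0103. TJP1, OCLN and GJA1 had no peak, and CDH2 was the 1 gene with a peak among 17 blood-testis barrier genes. GATA4 and GDNF, a transcription factor and a secreted growth factor of Sertoli cells, were the 2 genes with a peak among 18 Sertoli cell genes. The GATA4 peak lay 29.3 kb upstream with a fold enrichment of 3.06 and an FDR of 0.299. The GDNF peak lay 172 kb downstream with a fold enrichment of 3.87 and an FDR of 0.118. SOX9, AMH, WT1 and FSHR had no assigned peak. Among 12 granulosa and ovarian genes, ESR2 had a peak 4.81 kb downstream of its TSS, with a fold enrichment of 2.72 and an FDR of 0.489. RUNX1 had peaks 221 kb and 608 kb upstream, with fold enrichments of 2.72 and 3.08, and FOXL2 had none. HSD17B3, a testosterone-producing enzyme of Leydig cells in many mammals, had a peak 69.2 kb downstream with an FDR of 0.186. KDR, an endothelial receptor, had a peak 20.2 kb upstream with an FDR of 0.0346. The germ cell list, with 13 genes tested, and the retinoic acid list, with 8, had no peak. Random lists matched on gene length had a mean of only 1.07 and 0.755 genes with a peak, so this absence is no sign of depletion. With all assigned peaks, none of the 12 lists passed the test, and none had an unadjusted p under 0.05. With peaks of FDR under 0.05, 4 other lists had a member left, 1 gene each, and an odds ratio above 1. It was 5.81 for myoid and endothelial genes (KDR), 2.90 for barrier genes (CDH2), 2.44 for innate sensors (TLR1) and 1.22 for NF-κB pathway genes (MAP3K7), with an adjusted p of 1 in Fisher's exact test for each. With a fold enrichment of at least 5, CDH2 alone gave the barrier genes an odds ratio of 30.5 (Fisher's exact test, p = 0.0350, adjusted p = 0.270). Across the lists, 17 of 211 genes, 199 of which were in the gene table, had a peak. An FDR under 0.05 was reached at 7 genes, and 2 (TLR1 and ESR2) had a peak within 5 kb of the TSS. Of all protein-coding genes, 7.31% had a peak, so a single gene without one is the common outcome.

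TXK, a tyrosine kinase of T cells, had the highest fold enrichment of any named protein-coding gene, 5.79 at a peak 18.6 kb downstream of its TSS on chromosome 6 (67331479 to 67331695, FDR 0.000109). CDH2 and PDGFD, a platelet-derived growth factor, followed at 5.60, then FIGN at 5.59 and TBC1D30 at 5.57. WDPCP, a planar cell polarity effector, had a fold enrichment of 5.47 and the lowest FDR of the 10 highest genes, 4.18e-05. CH25H, which makes the oxysterol 25-hydroxycholesterol, reached 5.41, and F3 (tissue factor), SOX14 and TERF1 each reached 5.38. The peaks of PDGFD and TBC1D30 lay 4.94 kb and 5.53 kb from the TSS, and those of the other 8 genes lay at least 18.6 kb away.

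METTL15, FAT4 and LRRTM3 were the protein-coding genes with the most assigned peaks, with 8, 7 and 7. FAT4, an atypical cadherin, follows SPRY1 and ANKRD50 on chromosome 17 in the gene table. Its peaks lay 23.3 kb to 680 kb downstream of its TSS. Those of METTL15 lay 96.6 kb to 978 kb downstream on chromosome 15, and those of LRRTM3 lay 24.7 kb to 1426 kb upstream on chromosome 28. Over all gene kinds, the names with the most peaks were the tRNA names TRNAC-GCA with 84, TRNAC-ACA with 40 and TRNAS-GGA with 39. Each of these names stands for many gene copies, with 294, 117 and 132 entries in the gene table. The 2949 peaks with an assigned gene fell to 2102 gene names, of which 1504 were protein-coding, 7.31% of the 20566 in the table. Protein-coding genes took 64.6% of these peaks, pseudogenes 15.6%, tRNA genes 8.95% and long noncoding RNA genes 6.92%.

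Few peaks lay near promoters. Of the 2949 assigned peaks, 187 lay within 5 kb of a TSS, which is 6.34% (95% Wilson interval 5.52% to 7.28%), and 34 lay within 1 kb. The median distance to the TSS was 53.4 kb, with quartiles of 19.5 kb and 138 kb. Within 5 kb, 105 peaks lay upstream and 82 downstream of the TSS (exact binomial test, two-sided, p = 0.107). Within 10 kb, peak density was not detectably higher closer to the TSS. Of the 409 peaks within 10 kb, 187 were in the nearer 5 kb and 222 in the farther 5 kb (exact binomial test against an even split, two-sided, p = 0.0926). A further 190 lay between 10 kb and 15 kb and 75 between 45 kb and 50 kb. If peaks go to the nearest TSS, random positions also become rarer with distance, so an even split is only a rough reference. No random positions were drawn, so whether 6.34% within 5 kb is low was not tested. Stronger peaks were not detectably closer, since 6.05% of peaks with an FDR under 0.05 and 6.44% of the others lay within 5 kb (Fisher's exact test, p = 0.796). The peaks within 5 kb belonged to 174 genes, of which 118 were protein-coding, 91 of these with a gene name. Besides PDGFD and TLR1, those with high fold enrichment were HERC5, TTC23, MRPS5 and NANOG, which were picked after their values were seen. HERC5, an interferon-induced ligase, had a peak 2.39 kb upstream with a fold enrichment of 5.05 and an FDR of 0.00163. TTC23 had one 0.609 kb upstream at 4.87, and MRPS5 had one 1.82 kb downstream at 4.81. NANOG, a pluripotency factor, had one 1.78 kb upstream on chromosome 5, at 99877080 to 99877253, with a fold enrichment of 4.66 and an FDR of 0.00478. The authors' words for exon, intron and intergenic positions were not used, because 2830 of the 2949 assigned peaks were placed in the single exon of records that each held peaks over at least 29.7 Mb of an autosome.

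**Figure D3:**
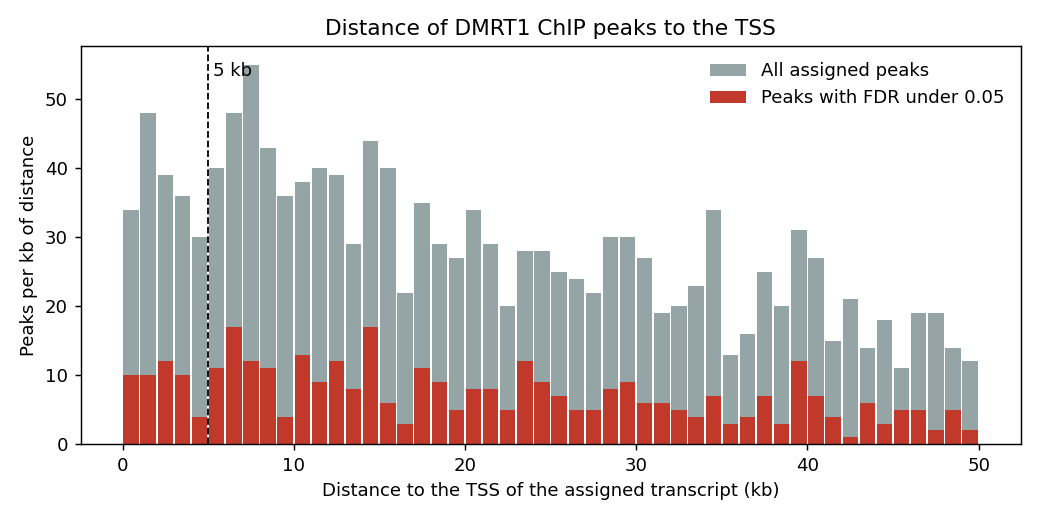
Number of DMRT1 ChIP peaks (y axis, per kb of distance) against distance to the TSS of the assigned transcript (kb, x axis), for assigned peaks within 50 kb. Grey bars are all assigned peaks, red bars those with an FDR under 0.05, and the dashed line marks 5 kb. The first kb holds 34 peaks, the eighth holds 55 and the last one shown holds 12.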

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

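The test of background in this part was chosen after the peaks were seen. A group of 278 peaks had no assigned gene and so entered none of the gene comparisons, and it stood out because it held strong signal. All 278 lay on unplaced sequences, which the naming of sequences by their assigned genes partly fixes, although by sequence name alone none lay on the 29 autosomes. Of the 278, 153 had an FDR under 0.05, and their median pileup was 13. Of the 22 peaks in the whole list with an FDR of at most 1e-05, 19 were among them.

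All 22 of these strongest peaks lay on unplaced sequences, and on chromosomes the lowest FDR was 2.18e-05 and the highest fold enrichment 6.10. A candidate explanation is high background, as at repeats whose copies are merged in an assembly, and 11 of the 22 had a background above 3.51, the 99th percentile on chromosomes. Chromosomes are an unlike reference, since all 293 peaks on unplaced sequences had a median background of 2.68. How many of these 293 exceeded 3.51 was not counted, so a high background is not shown to be particular to the strongest peaks. Of the 22, the 7 with a pileup of 50 or more had backgrounds of 11.6 to 91.2 and fold enrichments of 1.89 to 4.67. The 15 with a lower pileup had a median background of 1.82, against 1.78 on chromosomes, and fold enrichments of 4.05 to 7.43. At so low an FDR a low pileup requires a low background, so this split is no separate test. The strongest peaks outside those 11 had a background of at most 3.51 by definition, so the cutoff gives no separate evidence on them. For the set as a whole, which is mixed, high background stays open, as do binding and sequence content. No biological explanation was tested.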

How the results depend on the processing

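The settings with an FDR under 0.05 and with protein-coding genes only were chosen after the data were seen. An FDR of at most 1e-05 left 22 peaks and 3 genes, a fold enrichment of at least 5 left 119 peaks and 67 genes, and an FDR under 0.05 left 913 peaks and 626 genes, since each keeps part of the 3227 peaks and 2102 genes. The share of assigned peaks within reach of a TSS was 1.15% with a window of 1 kb, 66.7% of the 3 assigned peaks with an FDR of at most 1e-05, and 4.29% of the 70 with a fold enrichment of at least 5. It stayed inside its interval, at 6.05% to 6.35%, with an FDR under 0.05, chromosomes only or protein-coding genes only. All 3227 merged peaks shared at least 50% of the shorter interval with a called peak. No gene list passed with a fold enrichment of at least 5, an FDR under 0.05 or length-matched lists. At an FDR of at most 1e-05 no list gene had a peak, so the lists could not be tested there. The smallest adjusted p in Fisher's exact test was 0.128, for the MAPK feedback list at an FDR under 0.05 (odds ratio 7.37). Length matching was run on all assigned peaks only, where 4 members of that list had a peak against a mean of 1.88 in random lists (permutation p = 0.216 before adjustment). Settings of the motif and gene end results, and assignment of genes by a reference annotation, were not run. No paired analysis was possible because each group had 1 library. The low pileups limit how well single peaks are separated from background.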

Other observations

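The tests in this part were chosen after the peaks were seen. Protein-coding genes with an assigned peak were long, with a median length of 65.9 kb against 15.3 kb for those without. A peak was assigned to 3.21% of the shortest 10% of genes and to 23.7% of the longest 10% (Fisher's exact test, two-sided, p = 4.07e-91). Peaks were assigned at a median of 53.4 kb from the TSS, so genes with more sequence around them can collect more peaks wherever peaks fall. The test cannot tell this from a preference for long genes. Gene-poor autosomes tended to carry more peaks per Mb, as chromosome 9 did with 1.75, and gene-rich ones fewer, as chromosomes 19 and 25 did with 0.746 and 0.736. These examples are extremes of peak density, and not every chromosome followed. Chromosome 24, with 4.37 protein-coding genes per Mb, had 1.05 peaks per Mb. Across 29 autosomes, peaks per Mb and protein-coding genes per Mb had a Pearson's r of -0.70 (permutation p = 1.0e-05, the smallest 100000 resamples can give) and a Spearman's rho of -0.63 (permutation p = 4.1e-04). Without chromosomes 18 and 19, the farthest in gene density, r was -0.62 (permutation p = 4.2e-04) and rho -0.54 (permutation p = 4.3e-03). The end of the last peak stood in for chromosome length, and it divides both measures.

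The X chromosome carried 15 peaks, 0.145 per Mb against 1.21 on autosomes, and 86.6 would be its part by protein-coding genes (exact binomial test, two-sided, p = 2.18e-21), though gene share is a rough guide since peaks run against gene density. Per Mb it lay below the lowest autosome, chromosome 25 at 0.736 (exact binomial test, two-sided, p = 1.40e-07), which argues against chance. Per 100 genes its 2.59 was not detectably below the 3.98 of chromosome 19 (exact binomial test, p = 0.174). That chromosome is far richer in genes, at 18.7 per Mb against 5.62 on the X. Chromosomes 4 and 8, closest to the X in gene density at 5.44 and 5.68 per Mb, carried 26.4 and 20.3 peaks per 100 genes. Male cells have a single X, and lower coverage from 1 copy is a candidate explanation that could leave fewer positions past the caller's threshold. As lower coverage would give, 66.7% of the X peaks were at the background floor, against 13.6% on autosomes (Fisher's exact test, two-sided, p = 3.64e-06). Median pileup, however, was 9 on both. Median fold enrichment was higher on the X, at 4.30 against 3.59. An FDR under 0.05 was reached by 9 of the 15 X peaks, or 60% (Wilson interval 35.7% to 80.2%), against 25.5% on autosomes. Median background was 1.32 on the X and 1.78 on autosomes. At equal pileup a lower background gives a higher fold enrichment and a lower FDR. Neither difference is therefore separate from the share of peaks at the floor. These values cover only peaks that passed the caller, so they do not measure coverage of the X. Whether DMRT1 binds less often on the X stays open, and some X sequence may be among the unplaced sequences.

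The 1 Mb centred on the SPRY1 TSS held 7 peaks, 5 of them assigned to SPRY1, where even placement on chromosome 17 gave a mean of 1.58 (one-sided permutation p = 0.00080, 10000 draws). Peaks were clustered on autosomes in general (variance over mean 1.64 in 2389 windows of 1 Mb), so even placement is a weak reference. Only 11 of these windows, or 0.460%, held as many peaks, with a median of 1 and a maximum of 8. The SPRY1 count was therefore high among these windows too. The window was, however, placed on the gene the study names, after its many peaks were seen. Neither comparison therefore tests a neutrally chosen position. Gene-poor surroundings were not tested. The same window around FAT4, farther along chromosome 17, held 8 peaks, 5 of them with an FDR under 0.05. FAT4 was named for its many peaks, so it is no neutral comparison. With peaks of FDR under 0.05 the SPRY1 window held 1 peak, with a further SPRY1 peak just outside at 513 kb, and even placement gave a mean of 0.388 (one-sided permutation p = 0.324), so no excess was detectable with so few peaks. Why the SPRY1 window was among the fuller ones with all peaks stays open, and no biological explanation was tested.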
